A study of Mus musculus with 4 samples.

How the data were processed

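C2C12 mouse myoblasts were profiled in 2 conditions with 2 arrays each. Per the labels, the growth cells were kept in medium with 10% fetal bovine serum and collected at 60 to 70% confluency, and the differentiation cells were moved to 2% horse serum at confluence and collected after 24 h. Groups and replicate numbers were taken from the sample titles. The series' design text calls the arrays of a condition biological replicates, and the cultures behind them are not described further.

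The deposited table holds 1 linear intensity per transcript cluster and array, made with PLIER and the mouse genome build mm9, per the submitters' processing notes; PLIER combines the probes of a cluster into 1 value. Background correction, normalization between arrays and the PLIER version are not given in the sources used here. The values range upward from 0 and hold no detection call, so a dim value cannot be told from background. Median intensities were 167.8, 177.2, 174.1 and 170, and whether the arrays had been scaled to each other is not known. Of the 16658 clusters, 225 were listed at 0 on at least 1 array and 5 on all 4. Signal near the floor carries little information, and no depth applies to arrays.

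Clusters were named from the platform annotation: 14938 carried 1 gene symbol, 989 carried several and 731 were listed with none. Entrez identifiers of 14883 of those with 1 symbol were found in a RefSeq gene table of assembly GRCm38.p6, which changed no symbol. That table was otherwise used for the order of neighbouring genes and for ranking genes by genomic span, and none of its coordinates are given because its build differs from that of the arrays. Where several clusters named a gene, the brightest over all 4 arrays was used for gene lists, which left 14806 genes. Myh3 shared its cluster with other genes and is therefore not reported, and Nudt21 was not among the clusters named.

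Intensities were transformed as log2(value + 16) with no further normalization or filter. The 2 groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), with Benjamini-Hochberg adjustment over all clusters and a threshold of 0.05. No pairing or covariate was used. The 27 gene lists were compared with all other genes by limma's camera with a preset correlation between genes of 0.01, adjusted over the lists. Camera with an estimated correlation and limma's fry, which tests whether a list's genes move on balance in 1 direction without comparing them with other genes, were run beside it. Genes on more than 1 list were Cdkn1c, Hes1, Hey1 and Heyl. The design, the lists, the alternatives and the rule for naming genes were fixed before the data were examined. The rule takes the 12 largest rises and the 12 largest falls past the threshold with the arrays of the groups apart (clone names left out), up to 4 genes per list by adjusted p, 13 genes chosen as checks of the labels or for the 3' end machinery, and each gene of a count of 5 or fewer.

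The alternatives were quantile normalization, median centring, an offset of 1, leaving out the lowest-intensity clusters (2 filters), an intensity trend or a robust prior in eBayes, the replicate number as a block, leaving out each array in turn, a test against a minimum change of 1.5-fold (limma's treat), the mean over all clusters of a gene, and both other list tests. Leaving out clusters listed at 0 was added after seeing the data. Where an array was left out, its group kept 1 array, which was assumed to vary like the other group.

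The procedure was tested on simulated data with 200 changed clusters among 16658. It recovered 31% of 2-fold and 98% of 4-fold changes, 12 of its 141 calls were unchanged clusters, and it called 0 with no change present. The changed clusters were drawn only from those above the median growth intensity, and changes were set on the scale of log2(value + 16). The recovery therefore does not cover dim clusters. In the simulation of the lists the shifted list was called, as was 1 of 26 unshifted lists. Its noise was drawn independently for each cluster and its lists were random genes. It therefore does not give the rate of false calls for lists whose genes are correlated. Because 16.2% of clusters were called in the real data, far more than were changed in the simulation, the adjustment was less strict there. The 31% therefore does not give the recovery in these data, where changes under 2-fold were called, such as Kdm2a (log2 change 0.70). With 2 arrays against 2, some 2-fold changes can still miss the threshold.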

Results

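Total RNA from C2C12 cells, a mouse myoblast line that withdraws from the cell cycle and forms multinucleated muscle fibres when serum is lowered, was hybridised to 4 Affymetrix mouse exon arrays. There were 2 growth arrays, from cells collected at 60 to 70% confluency in medium with 10% fetal bovine serum. The 2 differentiation arrays were from cells moved at confluence to 2% horse serum and collected after 24 h. Cell density and the amount and kind of serum thus differ together with the condition, and their effects cannot be told apart from those of differentiation. The labels call the 2 arrays of each condition biological replicates. Each array gave 16658 intensities, 1 per transcript cluster, and 14938 of the clusters carried a single gene symbol. The median intensity was 167.8 and 177.2 on the growth arrays and 174.1 and 170 on the differentiation arrays. Across clusters, log2 intensities correlated at 0.984 between the growth arrays, at 0.986 between the differentiation arrays and at 0.939 to 0.951 between arrays of different conditions, where clusters are not independent replicates. The number of arrays, 2 per group, limits the precision of every value. All changes below are differentiation minus growth on the scale of log2(intensity + 16), which understates the change of dim genes, with the limma standard error (SE). Intensities are means ± SD (n = 2). Arrays were left out singly, so a value without either array of a condition, or without any of the 4, is one found each time such an array was left out.

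The study asks how gene expression, and in particular the choice of mRNA 3' ends, changes as myoblasts start to differentiate. The cartilage matrix protein gene Cilp rose most, from 17.7 ± 5.78 to 531 ± 54.6 (log2 change 4.03 ± 0.20 SE). The protein cross-linking enzyme gene Tgm2 rose by 3.38 ± 0.19, and Aspn and Dcn, which encode small leucine-rich proteoglycans of the matrix, rose by 3.12 ± 0.22 and 2.98 ± 0.22. Next came Ncf4, a subunit of the phagocyte NADPH oxidase (2.96 ± 0.31), Rgs2, a regulator of G protein signalling (2.93 ± 0.18), and the Notch ligand Dll1 (2.82 ± 0.19). The remaining 5 of the 12 largest rises were Hsd11b1, which regenerates active glucocorticoid (2.75 ± 0.18), the secreted proteases Htra3 (2.57 ± 0.19) and Adamts16 (2.55 ± 0.22), the orphan receptor Gpr153 (2.51 ± 0.18) and Fez1, an adaptor of axonal transport (2.48 ± 0.18). The 12 largest falls were led by the mismatch repair exonuclease gene Exo1 (-3.54 ± 0.20), the G1/S cyclin gene Ccne2 (-3.45 ± 0.20) and the origin licensing gene Cdc6 (-3.39 ± 0.19). Depdc1b (-3.38 ± 0.20), the chromatin remodeller Hells (-3.38 ± 0.20) and the replicative helicase subunits Mcm5 (-3.33 ± 0.18) and Mcm3 (-3.25 ± 0.18) followed. The others were Pclaf, which encodes a PCNA-binding factor (-3.22 ± 0.19), the Fanconi anaemia gene Fancb (-3.18 ± 0.18), the mitotic kinase gene Pbk (-3.16 ± 0.20), the linker histone gene H1f1 (-3.15 ± 0.18) and the smooth muscle calponin gene Cnn1 (-3.13 ± 0.21).

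In all, 1439 transcript clusters were higher and 1252 lower in differentiation (limma with Benjamini-Hochberg adjustment over 16658 clusters), which is 16.2% of those tested. Of these, 579 were at least 2-fold higher and 627 at least 2-fold lower. For each of them both differentiation arrays lay on the same side of both growth arrays. Over all clusters the arrays of the 2 groups did not overlap for 60.8%, against 33.3% by chance. The adjusted p of the 24 genes with the largest changes was 0.000158 to 0.000787, and all 24 passed the threshold under each alternative in which they were tested. The counts rested on the arrays used. They were 523 higher and 739 lower without growth replicate 1 and 1189 and 839 without growth replicate 2. They were 314 and 458 without differentiation replicate 1, and 305 and 446 without differentiation replicate 2. With an offset of 1 in place of 16 they were 528 and 622, with an intensity trend in the variance prior 2415 and 1947, and against a minimum change of 1.5-fold 204 and 355.

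The lists for the contractile apparatus and for the acetylcholine receptor and excitation-contraction coupling were shifted higher. Of 27 gene lists fixed before the data were examined, 9 were shifted higher and 5 lower (limma camera with a preset correlation between genes, Benjamini-Hochberg adjusted over the 27 lists). None passed when that correlation was estimated from these arrays. That version of camera rests on the residual degrees of freedom of only 4 arrays, so it has little power. Replication-dependent histones, with an estimated correlation of -0.141, below the preset, went from an unadjusted camera p of 2.26e-05 to 0.0483. Estimates for the muscle transcription factor, Notch, and insulin-like growth factor and imprinted gene lists were also below the preset. The other called lists had estimates of 0.093 (glycolysis and hypoxia) to 0.39 (DNA replication and G1/S), above the preset of 0.01. Their p values with the preset correlation may therefore be too small. Because of its low power, camera with an estimated correlation does not decide whether the shifts hold. Of 37 measured genes of the contractile apparatus, 19 rose and none fell (22 rose when adjusted over the list alone), with a median log2 change of 0.70 (camera adjusted p = 4.08e-08; adjusted p = 0.324 with an estimated correlation). Actn3, the fast-fibre alpha-actinin, rose from 196 ± 19.2 to 782 ± 108.6 (1.91 ± 0.19 SE), the Z-disc protein gene Pdlim3 rose by 1.49 ± 0.18, the thin-filament capping gene Tmod1 by 1.34 ± 0.18 and the myosin chaperone gene Unc45b by 1.55 ± 0.21. Of 29 genes of the acetylcholine receptor and of excitation-contraction coupling, 15 rose and none fell (19 rose when adjusted over the list alone), with a median of 0.86 (camera adjusted p = 3.21e-08; adjusted p = 0.324 with an estimated correlation). The fetal receptor subunit gene Chrng rose from 742 ± 20.6 to 2449 ± 2.16 (1.70 ± 0.18), Chrnd, another subunit, rose by 1.28 ± 0.18, and Trdn and Casq2, of the calcium release complex, rose by 2.10 ± 0.24 and 1.24 ± 0.18. The contractile count and the receptor and coupling count were each 8 genes with an offset of 1. Fewer genes of both lists also passed without growth replicate 1, differentiation replicate 1 or differentiation replicate 2. The medians moved less. With an array left out they were 0.613 to 0.744 for the contractile list and 0.711 to 0.978 for the receptor and coupling list. Of the 8 genes named here, Casq2 alone lost its call when an array was left out (differentiation replicate 2).

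The list of muscle transcription factors was shifted higher. Of 22 measured, 6 rose and none fell (9 rose and 1 fell when adjusted over the list alone), with a median of 0.35 (camera adjusted p = 0.0255; adjusted p = 0.324 with an estimated correlation). The differentiation factor gene Myog rose from 674 ± 38.6 to 1785 ± 148.4 (1.38 ± 0.18 SE; limma adjusted p = 0.00237), and Myod1, a determination factor, from 1230.5 ± 68.4 to 2299 ± 185.2 (0.89 ± 0.18; adjusted p = 0.0155). Smyd1, a muscle methyltransferase gene, rose by 1.08 ± 0.20. Mef2d, a partner of the MyoD family, rose by 1.07 ± 0.22 from 0.59 and 5.17 on the growth arrays to 18.3 and 29.0 on the differentiation arrays, all dim. The size of this change depends on the offset and was 2.94 with an offset of 1. Myf5, the other determination factor, changed by 0.13 ± 0.18 and did not pass (adjusted p = 0.639). The count fell to 1 gene with an offset of 1 and without growth replicate 1, differentiation replicate 1 or differentiation replicate 2. In those 4 settings the calls of Myod1, Smyd1 and Mef2d were lost, and the list's own call was lost under the milder of 2 filters on dim clusters.

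Lists for cell fusion and muscle energy supply did not pass in the main analysis. Of 28 genes of myoblast adhesion and fusion, 7 rose and 1 fell (9 and 1 when adjusted over the list alone; camera adjusted p = 0.0981). The fusion protein gene Mymk rose from 1109 ± 23.0 to 2763 ± 556.5 (1.29 ± 0.20 SE), Ptgfrn rose by 1.08 ± 0.18 and the cadherin gene Cdh11 by 0.94 ± 0.18, while the metalloprotease gene Adam12 fell (-1.50 ± 0.18). Among 22 genes of muscle energy metabolism 5 rose and none fell (5 and 1 when adjusted over the list alone; camera adjusted p = 0.0613). These were the creatine kinase gene Ckm, from 172 ± 5.63 to 404 ± 12.4 (1.16 ± 0.18), the glycolytic mutase gene Pgam2 (1.52 ± 0.23), Hjv, which encodes the iron regulator hemojuvelin (1.27 ± 0.18), the glycogen phosphorylase gene Pygm (0.83 ± 0.18) and the myoglobin gene Mb (0.78 ± 0.21). The number of risen fusion genes was 3 with an offset of 1, and 2, 1 and 0 without growth replicate 1, differentiation replicate 1 and differentiation replicate 2. That of energy genes was 3, 3, 1 and 2. The energy list as a whole passed without growth replicate 1 (camera adjusted p = 0.0264), with the dimmest clusters left out and with fry, and the fusion list passed with an intensity trend in the prior. Among the genes named, Adam12 and Hjv alone kept their calls with any 1 array left out. Pygm lost it without any of the 4, and Cdh11 and Mb without growth replicate 1 or either differentiation array. Ptgfrn and Pgam2 lost it without either differentiation array, Mymk without differentiation replicate 2 and Ckm without differentiation replicate 1.

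**Figure D1:**
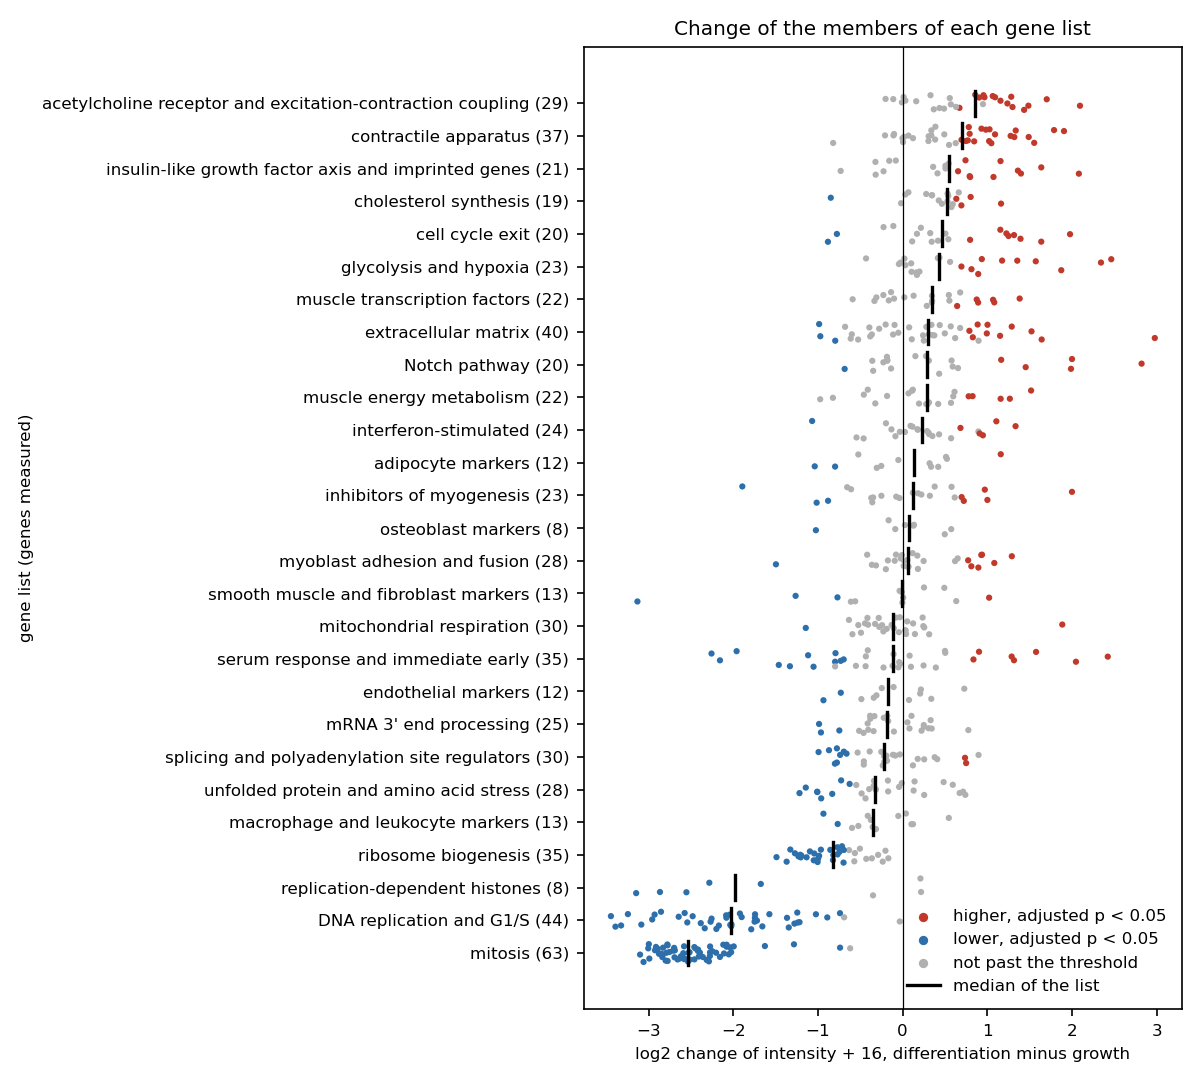
Log2 change of intensity + 16 (differentiation minus growth, horizontal axis) of each measured member of the 27 gene lists, with 1 point per gene, coloured by its call, and a black bar at the list's median; lists are ordered by median. Mitosis and DNA replication sit at medians of -2.54 and -2.03, and the receptor and coupling list, at 0.86, has the highest median.

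Genes of the cell cycle fell almost without exception. Of 44 genes of DNA replication and the G1/S transition, 42 fell and none rose (43 fell when adjusted over the list alone), with a median of -2.03 (camera adjusted p = 2.2e-35; adjusted p = 0.324 with an estimated correlation). Mcm5 fell from an intensity of 1860 ± 78.1 to 171 ± 3.25. Of 63 mitosis genes, 62 fell and none rose (63 fell when adjusted over the list alone), with a median of -2.54 (camera adjusted p = 1.83e-53; adjusted p = 0.324 with an estimated correlation). The mitotic kinase genes Aurkb (-3.10 ± 0.19 SE) and Aurka (-2.91 ± 0.18) fell, as did Fbxo5, an inhibitor of the anaphase-promoting complex (-2.99 ± 0.18). The cytokinesis motor gene Kif23 fell from an intensity of 2043 ± 148.5 to 241 ± 0.0424. Mki67, the proliferation marker, fell from 454 ± 123.8 to 80.1 ± 16.1 (-2.28 ± 0.24; limma adjusted p = 0.000790). Of 8 replication-dependent histone genes 5 fell and none rose (the same number when adjusted over the list alone), with a median of -1.98 (camera adjusted p = 8.73e-05; adjusted p = 0.324 with an estimated correlation). They were the linker histone genes H1f1, H1f5 (-2.87 ± 0.19) and H1f3 (-2.55 ± 0.20), H4c14 (-2.28 ± 0.18) and H2ax (-1.68 ± 0.21). Each of these counts stayed within 1.5 times its size whichever array was left out, and the named genes kept their calls.

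The list of genes that restrain the cell cycle was shifted higher. Of 20 genes of cell cycle exit, 8 rose and 2 fell (9 and 2 when adjusted over the list alone), with a median of 0.46 (camera adjusted p = 0.000699; adjusted p = 0.392 with an estimated correlation). Zfp36l1, which encodes an mRNA decay factor, rose by 1.98 ± 0.21 SE, the CDK inhibitor gene Cdkn1c from 51.1 ± 11.3 to 191 ± 3.25 (1.64 ± 0.20), the Myc antagonist gene Mxd4 by 1.39 ± 0.19 and the antiproliferative gene Btg2 by 1.32 ± 0.18. Cdkn1a, the p21 gene, rose from 1711 ± 99.2 to 2982 ± 49.4 (0.80 ± 0.18; limma adjusted p = 0.0216). The 2 that fell were the CDK inhibitor gene Cdkn2c (-0.88 ± 0.19) and the stress-response gene Gadd45g (-0.78 ± 0.20). Without differentiation replicate 2 the number that rose was 4; the number that fell was 1 without growth replicate 1 and 0 without any other array or with an offset of 1. The call of Cdkn1a was lost with an offset of 1 and without growth replicate 1 or either differentiation array.

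The Notch pathway list was shifted higher, while genes known to hold back myogenesis went both ways. Of 20 Notch genes 5 rose and 1 fell (8 and 1 when adjusted over the list alone), with a median of 0.29 (camera adjusted p = 0.0208; adjusted p = 0.324 with an estimated correlation). The ligand gene Dll1 rose from 64.6 ± 5.21 to 555 ± 68.1, the target gene Heyl rose by 2.00 ± 0.18 SE, Dtx4, of the Deltex ubiquitin ligases, by 1.99 ± 0.18, the receptor gene Notch3 by 1.45 ± 0.18 and Hes6, a Hes family member known as an antagonist of Hes1, by 1.16 ± 0.20. Lfng, a glycosyltransferase that modifies Notch, fell (-0.69 ± 0.18). Of 23 inhibitors of myogenesis 5 rose and 3 fell (7 and 4 when adjusted over the list alone; camera adjusted p = 0.617). Heyl, which is on both lists, the zinc finger repressor genes Zeb1 (1.00 ± 0.18) and Snai2 (0.97 ± 0.18), Bhlhe41 (0.72 ± 0.18) and Sox9 (0.70 ± 0.19) rose. The G1 cyclin gene Ccnd1 fell from 3296 ± 108.7 to 876 ± 67.5 (-1.89 ± 0.18), as did the histone methyltransferase gene Ezh2 (-1.02 ± 0.18) and Id1, an inhibitor of bHLH factors (-0.88 ± 0.20). The inhibitor counts were 1 higher and 2 lower with an offset of 1, 3 and 2 without either growth array, and 1 and 1 without either differentiation array. The calls of Hes6, Zeb1, Snai2 and Ezh2 were lost without either differentiation array, and those of Lfng, Bhlhe41, Sox9 and Id1 without any of the 4 arrays.

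The deposited values hold 1 intensity per transcript cluster, so the position of mRNA 3' ends was not measured here. The genes of the machinery that makes them were measured. Of 25 genes of mRNA 3' end processing, 3 fell and none rose (the same numbers when adjusted over the list alone), with a median of -0.18 (camera adjusted p = 0.209). Cstf2, the cleavage stimulation factor subunit known as CstF-64, fell from 1274.5 ± 56.7 to 649 ± 107.2 (-0.97 ± 0.20 SE; limma adjusted p = 0.0149). The genes of 2 subunits of the cleavage and polyadenylation specificity factor, Cpsf4 (-0.99 ± 0.21; adjusted p = 0.0192) and Cpsf2 (-0.75 ± 0.19; adjusted p = 0.0319), also fell. The Cstf2 paralog Cstf2t had a change of 0.78 ± 0.23, just outside the threshold (adjusted p = 0.0530). It passed under quantile normalization (limma adjusted p = 0.0438), median centring, both filters on dim clusters and an intensity trend in the prior. It also passed with the replicate block and without clusters listed at 0, but not with a robust prior or against a minimum change of 1.5-fold. Cpsf6 (-0.41 ± 0.20; adjusted p = 0.188), Cstf3 (-0.41 ± 0.19; adjusted p = 0.176) and Pcf11 (-0.18 ± 0.24; adjusted p = 0.621), which encode other cleavage factors, did not pass, though Cpsf6 did with an intensity trend in the prior. Of 30 splicing and polyadenylation site regulators, 8 fell and 2 rose (8 and 3 when adjusted over the list alone; camera adjusted p = 0.0624). Mbnl3 (-0.99 ± 0.20), which encodes a muscleblind protein, the SR protein gene Srsf2 (-0.87 ± 0.19), the polypyrimidine tract-binding gene Ptbp1 (-0.80 ± 0.19) and the U2AF subunit gene U2af2 (-0.78 ± 0.18) fell, while Celf2 (0.74 ± 0.18) and the epithelial splicing regulator gene Esrp1 (0.75 ± 0.19) rose. With an offset of 1 no member of either list passed. Every change named in this paragraph lost its call without differentiation replicate 1 and without differentiation replicate 2. In the first list 1 gene fell without either growth array, and Cstf2t rose without growth replicate 2. In the second, 1 gene fell without growth replicate 1 and none without growth replicate 2. The second list as a whole passed without growth replicate 1 (camera adjusted p = 0.0225), with an intensity trend in the prior and with the lower-intensity clusters left out.

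**Figure D2:**
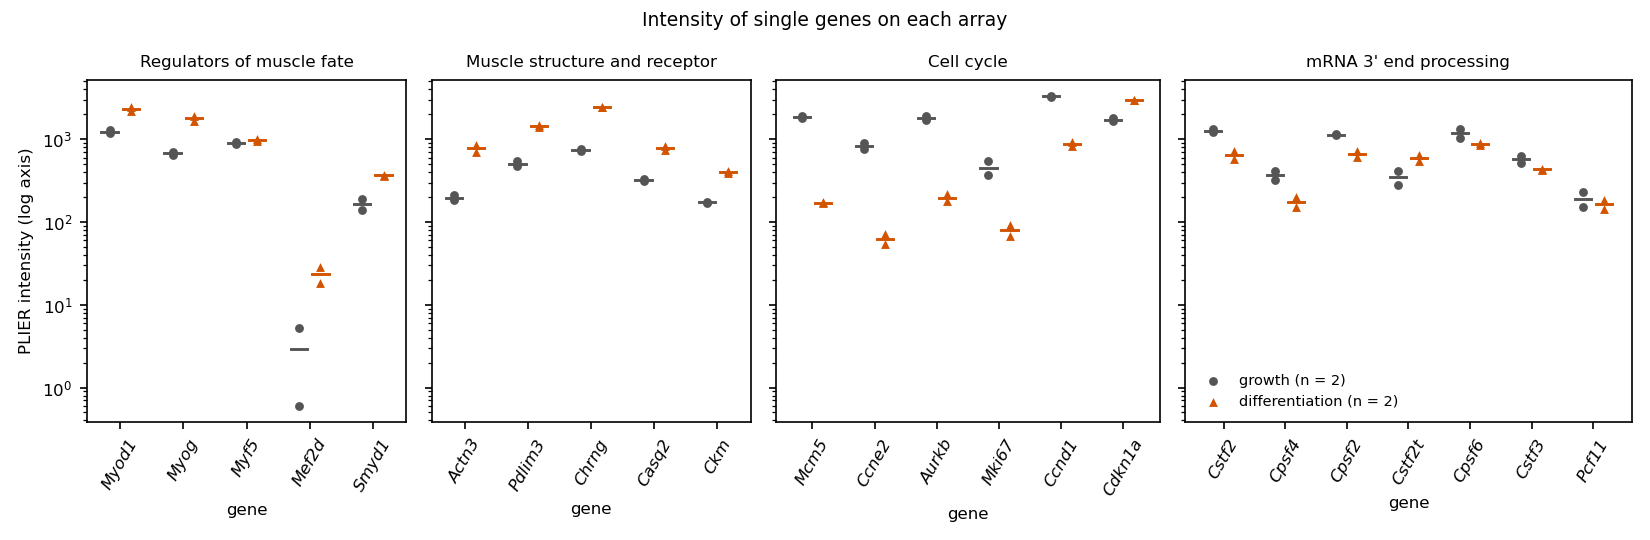
Intensity (log axis) of single genes on the 2 growth arrays (grey circles) and the 2 differentiation arrays (orange triangles), with a line at each mean, for regulators of muscle fate, muscle structure and receptor genes, cell cycle genes and genes of mRNA 3' end processing. Mcm5 drops from a mean of 1860 to 171 and Chrng climbs from 742 to 2449, while the 2 Pcf11 groups overlap.

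Genes that build ribosomes fell together. Of 35 genes of ribosome biogenesis, 25 fell and none rose (29 fell when adjusted over the list alone), with a median of -0.82 (camera adjusted p = 9.12e-14; adjusted p = 0.324 with an estimated correlation). The snoRNP gene Nop56 fell from 3477 ± 17.8 to 1230.1 ± 120.6 (-1.49 ± 0.18 SE), the growth regulator Myc from 1745 ± 33.0 to 666 ± 40.3 (-1.37 ± 0.18). Tcof1, which encodes a nucleolar factor of rRNA synthesis (-1.33 ± 0.18), and the processing factor gene Nop16 (-1.27 ± 0.19) fell too. Of 28 genes of the unfolded protein and amino acid stress responses 8 fell and none rose (9 fell and 4 rose when adjusted over the list alone), with a median of -0.33 (camera adjusted p = 0.0255; adjusted p = 0.523 with an estimated correlation). The 4 named members are enzymes of serine, one-carbon and asparagine metabolism. Shmt2 (-1.22 ± 0.18), Mthfd2 (-1.14 ± 0.18), Asns (-1.01 ± 0.18) and Psat1 (-0.96 ± 0.19) fell. The ribosome count was 13 genes and the stress count 3 with an offset of 1. Fewer genes of both lists also passed whichever array was left out. The medians moved less. With an array left out they were -0.875 to -0.818 for the ribosome list and -0.383 to -0.228 for the stress list. The stress list lost its own call without growth replicate 2 or differentiation replicate 1 and with limma's fry. Among these genes Nop16 lost its call without differentiation replicate 2, Mthfd2 without differentiation replicate 1, Asns without either differentiation array and Psat1 without those or growth replicate 2.

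The lists for glycolysis and hypoxia and for cholesterol synthesis were shifted higher, and that for the respiratory chain did not pass. Of 23 glycolysis and hypoxia genes, 10 rose and none fell (11 rose when adjusted over the list alone), with a median of 0.44 (camera adjusted p = 6.65e-05; adjusted p = 0.324 with an estimated correlation). The aldolase gene Aldoc rose from 64.8 ± 13.1 to 427 ± 9.98 (2.46 ± 0.19 SE), Pdk1, which encodes an inhibitor of pyruvate oxidation, by 2.34 ± 0.21, the lactate exporter gene Slc16a3 by 1.87 ± 0.18 and the mitophagy gene Bnip3 by 1.57 ± 0.19. Of 19 genes of cholesterol synthesis 4 rose and 1 fell (10 and 1 when adjusted over the list alone), with a median of 0.53 (camera adjusted p = 0.000969; adjusted p = 0.392 with an estimated correlation). The enzyme genes Mvd (1.16 ± 0.18), Cyp51 (0.80 ± 0.18), Hsd17b7 (0.69 ± 0.19) and Sqle (0.63 ± 0.18) rose, and Lbr, a sterol reductase that is also the lamin B receptor, fell (-0.85 ± 0.19). Of 30 genes of mitochondrial respiration 1 rose and 1 fell (the same numbers when adjusted over the list alone; camera adjusted p = 0.197). The coactivator gene Ppargc1a rose from 33.0 ± 17.7 to 161 ± 34.1 (1.89 ± 0.28), and the citric acid cycle gene Idh3a fell (-1.14 ± 0.19). Cox7b (-0.63 ± 0.19; limma adjusted p = 0.0609) and Cox10 (-0.59 ± 0.19; adjusted p = 0.0674) did not pass, though Cox10 did with either filter on dim clusters and with an intensity trend in the prior. With an offset of 1, and without growth replicate 1, differentiation replicate 1 or differentiation replicate 2, the glycolysis and hypoxia count was 6, 6, 5 and 4 genes. Cholesterol genes that rose numbered 1 with an offset of 1 and at most 1 without any of the 4 arrays. Ppargc1a and Idh3a lost their calls without differentiation replicate 1, Mvd without differentiation replicate 2, and Cyp51, Hsd17b7, Sqle and Lbr without any of the 4 arrays.

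The list of the insulin-like growth factor axis and imprinted genes was shifted higher, while genes of the matrix moved in both directions. Of 21 genes of the insulin-like growth factor axis and imprinted genes, 10 rose and none fell (13 rose when adjusted over the list alone), with a median of 0.54 (camera adjusted p = 0.00028; adjusted p = 0.324 with an estimated correlation). Igf1, the growth factor gene, rose from 329 ± 14.6 to 1455 ± 248.2 (2.08 ± 0.20 SE), the binding protein gene Igfbp5 from 1796 ± 46.6 to 4766 ± 399.5 and the receptor gene Igf1r by 1.36 ± 0.18. The imprinted gene Cdkn1c is on this list too. Of 40 extracellular matrix genes 10 rose and 3 fell (15 and 7 when adjusted over the list alone), with a median of 0.29 (camera adjusted p = 0.0419; adjusted p = 0.632 with an estimated correlation). Dcn, the periostin gene Postn (1.52 ± 0.18), the laminin gene Lama4 (1.64 ± 0.20) and the gelatinase gene Mmp2 (1.29 ± 0.18) rose, while the protease inhibitor gene Timp1 (-0.99 ± 0.18) and the collagen genes Col6a3 (-0.97 ± 0.21) and Col18a1 (-0.80 ± 0.18) fell. The growth factor count was 4 genes with an offset of 1, and 5, 6, 4 and 5 without growth replicate 1, growth replicate 2, differentiation replicate 1 and differentiation replicate 2. The number of risen matrix genes was 5, 5, 9, 4 and 5 in the same settings. The matrix list lost its own call under quantile normalization, an offset of 1, both intensity filters and fry, and without growth replicate 1 or differentiation replicate 1. Timp1 lost its call without either differentiation array, Col6a3 without either growth array or differentiation replicate 2, and Col18a1 without any of the 4.

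Genes that answer serum moved in both directions. Of 35 serum response and immediate early genes, 11 fell and 7 rose (13 and 8 when adjusted over the list alone; camera adjusted p = 0.197). The orphan receptor gene Nr4a1 rose from 301 ± 22.8 to 1682 ± 93.3 (2.42 ± 0.18 SE) and the stress factor gene Atf3 by 2.05 ± 0.18, while the AP-1 gene Fosl1 fell (-2.16 ± 0.18), as did Ereg, which encodes an EGF family ligand (-2.26 ± 0.19). Interferon-stimulated genes as a list did not pass with camera but did with fry: 5 of 24 rose and 1 fell (6 and 1 when adjusted over the list alone; camera adjusted p = 0.0738; fry adjusted p = 0.00756). Irf7 (1.11 ± 0.21), Oasl2 (0.95 ± 0.20), Ifi27 (0.91 ± 0.20) and Stat2 (0.68 ± 0.19) rose and Mx1 fell (-1.07 ± 0.20). Parp14 rose by 1.33 ± 0.26 at intensities near the floor, from 0.01 and 10.1 to 31.2 and 40.3. The size of its change depends on the offset and was 3.44 with an offset of 1. The 4 serum genes kept their calls with any 1 array left out. Their list's counts were 6 lower and 5 higher with an offset of 1, 7 and 6 without growth replicate 2, 5 and 5 without differentiation replicate 1 and 6 and 5 without differentiation replicate 2. No interferon gene passed with an offset of 1 or without differentiation replicate 2. Mx1 alone passed without differentiation replicate 1, and 1 and 3 genes rose without growth replicate 1 and growth replicate 2.

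Lists of markers of other cell types did not pass in the main analysis. Of 8 osteoblast markers 1 fell, the homeobox gene Dlx3 (-1.02 ± 0.21 SE), and none rose (camera adjusted p = 0.808). Phex (0.57 ± 0.18), Ibsp (0.50 ± 0.20) and Sp7 (-0.17 ± 0.22) did not pass, though Phex did under quantile normalization (limma adjusted p = 0.0476) and under the milder filter on dim clusters. Among 12 adipocyte markers the lipase gene Lpl rose from 1442 ± 42.9 to 3240.4 ± 16.2 (1.16 ± 0.18), the adipogenic regulator Pparg (-1.04 ± 0.18) and the fatty acid binding protein gene Fabp4 (-0.80 ± 0.23) fell. The lipid droplet gene Plin1 (-0.52 ± 0.19) did not pass (camera adjusted p = 0.846 for the list). Plin1 and the endothelial gene Robo4 passed under the stricter filter. Of 13 smooth muscle and fibroblast markers 3 fell and 1 rose (camera adjusted p = 0.299). Cnn1 fell from 756 ± 47.5 to 72.8 ± 17.8, the actin-binding gene Tagln by 1.26 ± 0.19 and Cd34 by 0.77 ± 0.18, and Pi16, a fibroblast marker, rose by 1.02 ± 0.20. Of 12 endothelial markers Egfl7 (-0.94 ± 0.18) and the VEGF receptor gene Flt1 (-0.73 ± 0.18) fell, and Tek (0.73 ± 0.27) and Robo4 (-0.49 ± 0.20) did not pass (camera adjusted p = 0.383). Of 13 macrophage and leukocyte markers Ptprc (-0.94 ± 0.19), at intensities under 30, and Cd68 (-0.77 ± 0.20) fell, and Itgam (-0.60 ± 0.22) and Adgre1 (-0.52 ± 0.20) did not pass (camera adjusted p = 0.0981, and 0.0483 without growth replicate 2). Adjusted over the list alone, the counts were the same for 4 of the 5 lists, and 5 smooth muscle and fibroblast markers fell and 2 rose. Cnn1 alone among these called genes kept its call with any 1 array left out. The calls of Fabp4, Cd34 and Flt1 were lost without any of the 4 arrays, and those of Dlx3, Egfl7, Ptprc and Cd68 without growth replicate 1 or either differentiation array. Those of Lpl and Pparg were lost without either differentiation array, that of Pi16 without growth replicate 1 or differentiation replicate 1, and that of Tagln without differentiation replicate 1.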

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

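Of the alternatives, only leaving out clusters listed at 0 was chosen after the results were seen. No gene was called in opposite directions in the main analysis and any alternative. Of 146 named genes 131 were called, and 63 of these were called in every alternative in which they were tested. Leaving out 1 array ended the call of 62 and reversed none of the 131. The numbers of shifted lists stayed at 8 to 10 higher and 4 to 6 lower, except that with an estimated correlation, which has little power with 4 arrays, 0 were higher and 0 lower. Apart from that, 11 of the 14 called lists passed in every alternative; the exceptions were muscle transcription factors, extracellular matrix and unfolded protein and amino acid stress.

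The counts of 1439 higher and 1252 lower clusters became 528 and 622 with an offset of 1 and 2415 and 1947 with an intensity trend in the prior, and the cause was not tested. The test against a minimum change of 1.5-fold gave 204 and 355, all of them at least 2-fold changed; it asks for more than a change from 0. Under the stricter of the 2 filters on dim clusters 8329 clusters were tested. More of them were called, 1951 higher and 1593 lower, but 368 were at least 2-fold higher, since fewer were tested. Leaving out an array, which leaves fewer samples, gave 305 to 1189 higher and 446 to 839 lower clusters, and 305 to 863 at least 2-fold higher. Quantile normalization (1528 and 1299) and median centring (1496 and 1251) moved the counts little.

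With the replicate block, 1369 clusters were higher and 1195 lower, and 9 lists were higher and 5 lower. The deviations of arrays with the same number from their group means had a correlation of -0.037 across clusters. With 2 arrays per group the 2 pairs give the same single correlation, which cannot show whether the cultures were paired. The direction of the osteoblast markers, which never passed, changed with settings: the list's mean change was 0.010 with an intensity trend, where the test's direction turned, and -0.083 to 0.10 with an array left out, with -0.065 without differentiation replicate 2. Sp7 ranged from -0.41 to 0.077 and Pcf11 from -0.45 to 0.087 with an array left out. Neither passed in any setting, and the cause was not tested. No detection calls or probe values were used, so changes of dim genes such as Mef2d and Parp14 are uncertain.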

Other observations

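The gene families described here were found by a scan of 240 groups of genes that share the start of their symbol, chosen after the results were seen, as were the correlation with order along the cluster and the test of a culture further along. The scan used limma's camera with a preset correlation, and 9 groups passed. None did with an estimated correlation (smallest adjusted p = 0.967) or with fry (smallest adjusted p = 0.188). With 4 arrays the version with an estimated correlation has little power, so its result does not decide whether these groups shifted. Nuclear pore genes fell: 11 of 17 Nup genes were lower and none higher (median log2 change -0.86; camera adjusted p = 4.97e-06), among them Nup43 (-1.76 ± 0.23 SE), Nup85 (-1.53 ± 0.18) and Nup107 (-1.43 ± 0.18). Of 16 genes whose symbols start with Rad and a digit, which include the cohesin gene Rad21 besides repair genes, 8 were lower and the recombination gene Rad52 alone was higher (camera adjusted p = 0.0134). Rad54l (-2.54 ± 0.20), Rad51ap1 (-2.31 ± 0.20) and Rad54b (-2.23 ± 0.21) changed most, while Rad51b and Rad51d did not pass. Of 9 genes of the RNA exosome 3 were lower, namely Exosc8 (-1.72 ± 0.21), Exosc2 (-1.22 ± 0.18) and Exosc1 (-0.99 ± 0.18), and none higher (camera adjusted p = 0.0170). Without growth replicate 1, growth replicate 2, differentiation replicate 1 and differentiation replicate 2 the lower Nup genes numbered 8, 9, 7 and 5, and the lower Exosc genes 3, 3, 1 and 2; Rad genes lower were 6 without any of the 4, and 1 was higher without growth replicate 2 and none without any other.

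Groups of histone lysine demethylase genes and of lipid transporter genes of the ABCA family were shifted higher with the preset correlation, but not with an estimated correlation (adjusted p = 0.967 for each) or with fry (adjusted p = 0.188 for each). Of 15 Kdm genes 7 were higher, led by Kdm5b (1.77 ± 0.18 SE) and Kdm4b (1.35 ± 0.19), and Kdm8 was lower (-0.72 ± 0.18; camera adjusted p = 0.00921). Of 14 Abca genes 7 were higher (camera adjusted p = 0.0336). They included the neighbours Abca8b (1.28 ± 0.23), Abca8a (1.33 ± 0.19), Abca9 (2.08 ± 0.18), Abca6 (1.42 ± 0.22, dim at 3.33 ± 0.368 in growth) and Abca5 (0.94 ± 0.20) on chromosome 11, and Abca1 (1.57 ± 0.19) and Abca7 (0.70 ± 0.18), while Abca13 was lower (-1.32 ± 0.18). Without growth replicate 1, growth replicate 2, differentiation replicate 1 and differentiation replicate 2, the higher Kdm genes numbered 2, 5, 2 and 2 and the higher Abca genes 5, 5, 3 and 4, and Kdm8 lost its call whichever array was left out. With an offset of 1, 2 Kdm and 4 Abca genes were higher.

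Protocadherin beta genes, which encode neuronal cell adhesion proteins from a tandem cluster, were shifted higher in the same scan. Of 22 genes 10 were higher and none lower (median 0.57; camera adjusted p = 0.000866, but 0.967 with an estimated correlation and 0.188 with fry). These were Pcdhb12 and all of Pcdhb14 to Pcdhb22, by 1.08 to 1.69, whereas none of Pcdhb1 to Pcdhb11 nor Pcdhb13 passed. Without differentiation replicate 1 and differentiation replicate 2, 5 and 7 passed. With an offset of 1, which weighs dim members more, 7 passed and the median was 1.14. Order along the cluster and change correlated across genes, which are not independent replicates (Pearson r = 0.873; Spearman rho = 0.837, and 0.793 to 0.854 over the settings tried). The correlation was computed because that order had been seen, so it describes the order and does not test it. Of 10000 random lists matched on intensity 0% had as high a median, and the highest was 0.381. The family was picked for its rise and its members are not independent, so this share is not a chance level. Genes of like intensity did not rise by this much in general, which argues against an intensity trend. Cross-hybridisation among these similar genes stays open. The brighter members changed by 0.979 more than the dimmer (bootstrap 95% interval -0.146 to 1.47), which decides nothing because the scale shrinks changes of dim genes, and no probe sequences were used. A shared control of the later part of the cluster is a candidate explanation that was not tested.

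Long genes rose more often than they fell. In the tenth of genes with the longest genomic span, 260 were higher and 72 lower. Of those called, 78.3% were higher (exact Clopper-Pearson 95% interval 73.5 to 82.6), against 49% among other genes. The interval treats genes measured on the same arrays as independent, which they are not. It therefore does not measure the spread between cultures. Without genes on the fixed lists the share was 78.8% of 312 called genes. The lists held so few called long genes that leaving them out could hardly change the share, so known groups stay open. The longest genes had the higher median in 9 of 10 intensity classes. Their excess was 0.273 to 0.377 in classes 6 to 10, the brighter ones, which argues against intensity-dependent scaling there. In classes 1 to 5 it was -0.087 to 0.112. The share was 65.2% without differentiation replicate 1 (45 higher and 24 lower; 37.5% among other genes) and 77.1% without differentiation replicate 2 (64 and 19). Examples chosen after their values were seen are Dync1i1 (2.35 ± 0.21 SE), Sema6a (2.21 ± 0.20) and Tenm4, and a link between length and expression in non-dividing cells may be worth testing, with base composition still open because no genome was used.

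Growth array 2 lay nearer the differentiation arrays than growth array 1. Its median absolute log2 difference from them was 0.335, against 0.423, a gap of 0.0876. The median difference between the growth arrays did depend on intensity, from -0.0895 to 0.157 over 10 intensity classes. Quantile normalization narrowed this to -0.0365 to 0.0682 but left a gap of 0.0854 (bootstrap 95% interval over clusters 0.0793 to 0.091), which argues against intensity-dependent scaling as the whole cause. A culture further along would show lower mitosis genes and higher contractile genes. After quantile normalization the median log2 difference, growth array 2 minus growth array 1, was 0.0712 for mitosis genes (42 of 63 higher; bootstrap 95% interval over genes 0.0382 to 0.126), which goes against it. It was 0.089 for contractile genes (23 of 37 higher; -0.0138 to 0.162), an interval that includes 0. Resampling genes on a single pair of arrays does not measure the spread between cultures, so this explanation stays open. A difference between the cultures or hybridisations that was not tested also stays open.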
